A study of Mus musculus with 4 samples.

How the data were processed

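RNA of Th2-polarised mouse CD4+ T cells was read by RNA sequencing in 4 libraries, 2 from cultures with HU-308 and 2 from cultures with DMSO. Per the labels, total RNA was extracted with TRIzol and libraries were made with a SMARTER mRNA kit. The authors name Bowtie2 2.3.4.3, RSEM 1.3.1 and DESeq2 1.4.5 with GRCm38 (mm10), without saying which step each served; annotation release and strand setting are not stated. The read counts per gene are, per the file headers, unscaled whole numbers for each library; if RSEM made them, the authors rounded them. The FPKM values were made by the authors per kilobase of a deposited gene length and per 1 scaled depth for each library, which is not the column total. The signal columns are the authors' mean of scaled counts over the libraries of each group, as deposited. Recomputed group means came within 0.581% of them. The log2 fold change is, per the file headers and the values, the authors' ratio of HU-308 over DMSO, and its column is named after Cnr2. The p-value columns hold the authors' raw and adjusted p as deposited, for 23290 genes. Of 54532 gene identifiers, 54495 are in GENCODE mouse release 21 and 53585 have identical GRCm38 coordinates.

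Groups were taken from the labels before the data were examined. HU-308 was compared with DMSO, 2 libraries against 2, as unpaired samples with 2 residual degrees of freedom, since no label pairs libraries of the same number. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and genes were tested by the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 19.8%. The SE of a log2 fold change is its absolute value over the square root of F. CPM values are TMM-scaled. Named genes are the genes of the title, the 10 largest rises and falls past the threshold with a mean log2 CPM of at least 2, and up to 4 members per list; a few others complete a group whose count is given. Gzmb and Ighm are named as the marker that sets a list's level, and Foxp3 as the gene that defines its list. Results for a few called genes and list members are not reported here.

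Gene lists, 35 in all with 485 genes, of which 380 were tested, were written from general knowledge before the data were examined. They cover T helper states, cytokine signalling, activation, metabolism, stress, cell types and RNA quality. Lists with at least 3 tested genes (32) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with the correlation estimated, and with fry. The estimated correlation rests on 4 libraries. Members were also adjusted over the list alone. For the 32 lists, and for 2 lists written after the first results, FOXO-induced genes and ribosome biogenesis, the median was set against 10000 random lists matched in 10 bins of abundance and 5 of length.

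Alternatives were other size factors (RLE, library size only), no low-count filter, at least 1 CPM in at least 2 libraries, protein-coding genes only, a log2 fold change of at least 1, DESeq2 1.42.0, limma-voom, limma on log2 FPKM with pseudocounts of 1 and 0.1, a block for the replicate number, each library left out, and camera with estimated correlation. Offsets for gene length and GC content and the adjusted-deviance form of the edgeR test were added after the data were seen.

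The steps were tested on simulated data of 14316 genes with 200 changed genes in each of 5 sets, besides the genes of lowered lists. The edgeR test called 43.9% of genes with a true log2 change of 1, 85.7% at 2 and 95.1% at 3, and 0.0399% of unchanged genes. The list test found 25 of 25 lowered lists and called 0 of 475 unchanged lists of 15 genes. Genes were simulated independently of each other, so this does not measure false list calls where genes vary together. Each simulated gene had the spread of the fitted trend for its abundance. The rates per gene therefore do not cover genes that vary more than the trend, or effects shared by a library. Exon overlaps in GENCODE were examined for 57 title genes and called genes, and 18 shared exon bases with another gene. Among them Nek6 shares 3.78% of its exon bases with Psmb7, Tube1 6.15% with Wisp3, Spata5 8.13% with Nudt6 and Jak3 7.55% with Insl3, so their counts are less certain. Larger overlaps of Il5 (27.1%), Shroom3 (24.9%), Gpr65 (24.7%) and Bnip3 (22.3%) were with genes given no read in any library. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.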

Results

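RNA of mouse T helper 2 (Th2) cells was sequenced in 4 libraries, 2 from cells grown with HU-308 and 2 from cells grown with DMSO. HU-308 is a synthetic cannabinoid that selectively activates cannabinoid receptor 2 (CB2), the product of Cnr2. The labels place the wild-type cells in the bleomycin model of systemic sclerosis, a disease of skin and lung fibrosis. Naive CD4+ T cells were polarised towards Th2, restimulated through CD3 and CD28 on day 4 and collected 12 h later. The comparison asks how HU-308 during polarisation alters the Th2 transcriptome, with the JAK and SOCS3 pathway named by the study's title. No library came from cells without Cnr2 or with CB2 blocked. Effects through CB2 therefore cannot be told apart from other effects of HU-308. The DMSO libraries held 18041457 and 20479254 counts and the HU-308 libraries 16145298 and 16263077, with 20525 to 21319 genes detected per library. The labels do not say whether replicates came from separate animals or cultures, so p-values measure only the spread between these 4 libraries, which may be technical. Counts of the 2 DMSO libraries differed well beyond sampling noise (chi-square per degree of freedom 43.0), as did those of the 2 HU-308 libraries (29.3), so neither pair is a copy of the same reads; separate preparations of 1 culture would also differ this way.

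Cells grown with HU-308 held much less transcript of the type 2 cytokines Il13 and Il5 and much more of Bcl6 than cells grown with DMSO. Il13, a cytokine that drives mucus production and fibrosis, fell 12.9-fold, from 25.3 ± 6.82 CPM (TMM-scaled read counts relative to library size; mean ± SD, n = 2) to 1.96 ± 0.675. Il5, the growth factor of eosinophils, fell 11.5-fold, from 12.0 ± 1.61 to 1.04 ± 0.128 CPM, a fold that rests on 19 and 16 reads with HU-308. Bcl6, a transcriptional repressor that directs T follicular helper differentiation, rose 13.1-fold, from 2.42 ± 0.404 to 31.8 ± 3.29 CPM. Among 14316 tested genes, 12 rose and 33 fell at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). All 45 were protein-coding, changed at least 2-fold, and had both HU-308 libraries on the same side of both DMSO libraries. That separation was seen in 51.3% of tested genes and is given by chance for 33.3%. Adjusted p among the 45 lay between 0.0246 and 0.0495, and 2687 genes had an unadjusted p under 0.05, 1259 higher and 1428 lower with HU-308. The count depended on the test, since DESeq2 called 244 higher and 482 lower, including all 45, the authors' deposited table called 246 and 482, and limma on log2 FPKM none (2625 at an unadjusted p under 0.05 with a pseudocount of 1). It was 17 higher and 92 lower without DMSO replicate 1, 93 and 244 without DMSO replicate 2, 40 and 97 without HU-308 replicate 1, and 8 and 12 when scaled by library size only, which moved the median of all genes by 0.118 and put 60.0% rather than 73.3% of calls on the lower side. A fit without 1 library takes its spread from the other group alone (1 residual degree of freedom) and can call more genes, so a gene that passes only there is not counted as changed. Without HU-308 replicate 2, 7 of the 12 rises and 15 of the 33 falls remained past the threshold.

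Besides Bcl6, 11 genes rose. Otud1, a deubiquitinase, rose 6.49-fold, and Rnf144a, a ubiquitin ligase, rose 3.98-fold. Klhl24, an adaptor of a cullin ubiquitin ligase, rose 3.35-fold. Map2k6, the kinase that activates p38, rose 4.28-fold, from 11.9 ± 0.489 to 50.9 ± 2.67 CPM. Tcf7, which encodes the naive and memory T cell factor TCF1, rose 3.41-fold, from 12.6 ± 0.789 to 43.0 ± 1.43 CPM. Ripor2 rose 3.03-fold and Arhgef18 rose 2.91-fold. Baiap3 rose 5.01-fold and Ccng2, an unconventional cyclin of non-dividing cells, 2.58-fold. Tnfaip3, which encodes the NF-kB inhibitor A20, and Kif21b, a kinesin, completed the genes that rose (2.58-fold and 2.33-fold). Otud1, Klhl24, Kif21b, Ccng2 and Tnfaip3 were no longer past the threshold without HU-308 replicate 2 (edgeR adjusted p = 0.0507, 0.0595, 0.0641, 0.0733 and 0.0883), nor were Kif21b and Ccng2 without DMSO replicate 1 (0.0511 and 0.0512). Baiap3 shares 2.74% of its exon bases with Tsr3 on the opposite strand, so its counts are less certain where strand was not used.

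Among the 33 falls, Adcy4, an adenylyl cyclase that makes cAMP, fell 14.5-fold, from 44.4 ± 2.03 to 3.05 ± 0.707 CPM (log2 fold change −3.86 ± 0.23 SE, edgeR adjusted p = 0.0246). Hbegf, a ligand of the EGF receptor, fell 13.6-fold from 10.6 ± 0.393 CPM. That fold rests on 18 and 8 reads of Hbegf with HU-308, and its log2 fold change of −3.76 was −4.45 without HU-308 replicate 1 and −3.29 without HU-308 replicate 2. The actin-binding genes Shroom3 and Enah fell 12.4-fold and 6.71-fold. Nrp2, a receptor for semaphorins and VEGF, fell 6.69-fold, and Car12, a carbonic anhydrase, fell 6.40-fold. Ikzf4, which encodes the Ikaros family factor Eos, fell 6.11-fold, and Emilin2, an extracellular matrix glycoprotein, fell 4.53-fold. Smaller falls included the cytokine Il10 (3.56-fold), the shared IL-6 family receptor Il6st, the acid-sensing receptor Gpr65 and the desaturase Scd1. Without HU-308 replicate 2, these 4 were no longer past the threshold (edgeR adjusted p = 0.0521, 0.113, 0.0641 and 0.0654), and without HU-308 replicate 1 the falls of Dennd5a, Mei4, Myo10 and Nek6 were not.

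**Figure D1:**
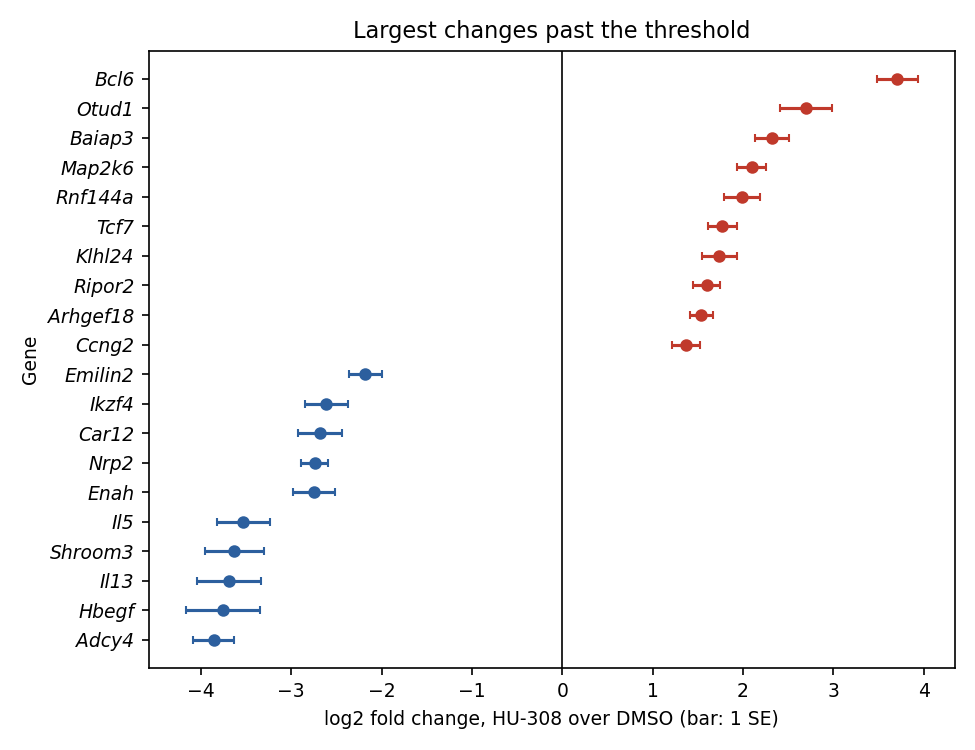
The 10 largest rises and 10 largest falls among genes past the threshold. Points give the log2 fold change of HU-308 over DMSO and bars 1 SE; Bcl6 lies farthest up at 3.71 and Adcy4 farthest down at −3.86.

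Of the genes named by the study's title, the Th2 cytokines stood well apart from the receptor and the kinases. Il4 (ENSMUSG00000000869), Il13 (ENSMUSG00000020383) and Il5 (ENSMUSG00000036117) lie close together on chromosome 11 of GRCm38, at 53602982 to 53618669, 53631324 to 53634702 and 53720794 to 53725106. Il13 had a log2 fold change of −3.69 ± 0.35 (SE) and Il5 of −3.53 ± 0.29, each with an edgeR adjusted p of 0.0389. Il4, the founding cytokine of the Th2 state, went from 27.1 ± 1.03 to 10.3 ± 0.818 CPM and narrowly missed the threshold (log2 fold change −1.40 ± 0.18, adjusted p = 0.0594). DESeq2 gave Il4 an adjusted p of 4.97e-05, and over the edgeR alternatives without 1 library it ranged from 0.0291 to 0.143. Gata3, the lineage factor of Th2 cells, went from 489.5 ± 4.42 to 343.5 ± 58.1 CPM (−0.51 ± 0.16, adjusted p = 0.192). Cnr2 (chromosome 4, 135895394 to 135920207) was expressed in every library, at 61.4 ± 11.3 CPM with DMSO and 112.8 ± 30.7 with HU-308 (0.88 ± 0.24, adjusted p = 0.152; DESeq2 adjusted p = 0.0211). Cnr1, the other cannabinoid receptor gene, had 1 read over the 4 libraries and was not tested.

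In the unpaired edgeR test neither Socs3 nor any Janus kinase gene passed the threshold. Socs3, a feedback inhibitor of cytokine signalling, stood at 170.4 and 420.0 CPM in the DMSO libraries and 81.3 and 148.2 in the HU-308 libraries (−1.36 ± 0.48, edgeR adjusted p = 0.221). Socs3 was higher in replicate 2 than in replicate 1 of both groups. Its log2 fold change was −1.89 without DMSO replicate 1 and −0.57 without DMSO replicate 2, the extremes over all settings. Jak1, Jak2 and Jak3 had log2 fold changes of −0.07 ± 0.24, 0.10 ± 0.22 and −0.05 ± 0.17, and Tyk2 of 0.30 ± 0.15. Stat6, the transducer of IL-4, was at 121.9 ± 5.0 and 126.3 ± 3.23 CPM (0.05 ± 0.13), Stat3 had a log2 fold change of −0.66 ± 0.21 (adjusted p = 0.192) and Socs1 of −0.11 ± 0.16.

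**Figure D2:**
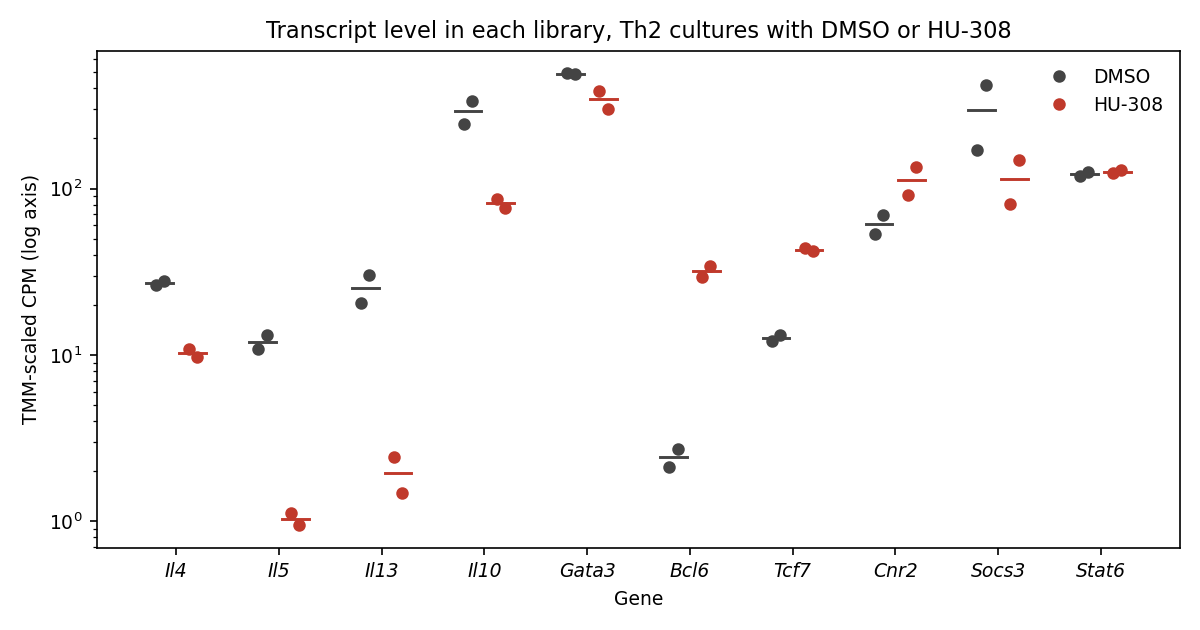
Transcript level of 10 genes in each library, in TMM-scaled CPM on a log axis. Points are single libraries (n = 2 per group) and short lines the group means; Il5 and Il13 sit near 1.04 and 1.96 CPM with HU-308, while Stat6 sits near 122 and 126 CPM in the 2 groups.

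Gene lists fixed before the data were examined were tested with camera at a preset inter-gene correlation of 0.01. Of 32 lists with at least 3 tested genes, 11 were lower and 3 higher with HU-308 relative to other genes. None of these 14 calls held when the correlation was estimated from the 4 libraries, where camera's smallest adjusted p was 0.332. Camera then refers its statistic to the 2 residual degrees of freedom, so few lists could pass. Calls were lost even where the estimated correlation was below the preset 0.01, as for glycolysis (−0.0351) and naive T cell genes (−0.063). Other called lists had higher estimates, among them 0.0197 for STAT5 targets, 0.136 for the Th2 program and 0.243 for the unfolded protein response. The highest was 0.869 for mitochondrial transcripts. The loss alone therefore does not show that genes vary together. Where the estimate lay above the preset, the p-values from the preset may still be too small. Fry, which tests whether a list's genes move on balance in a single direction, gave the 14 lists adjusted p between 0.10 and 0.415. Against 10000 random lists matched for abundance and length, the hypoxia and SOCS medians lay at percentiles 8.42 and 2.86, and those of the other 12 lists at 0.18 or lower or at 100.

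Among T helper states, the Th2 program stood out on the lower side. Of its 18 tested genes, 3 fell (Il5, Il13 and Il10) and none rose at the all-gene threshold, while 12 fell and 2 rose (Il17rb and Bhlhe41) adjusted over the list alone. The median log2 fold change was −0.68 (camera adjusted p = 6.32e-11, adjusted p = 0.332 with an estimated correlation). Il24 went from 917.8 ± 333.3 to 265.4 ± 9.74 CPM (−1.79 ± 0.27, edgeR adjusted p = 0.0679) and Il17rb, a receptor for IL-25, from 17.5 ± 4.15 to 38.6 ± 1.84 CPM (1.14 ± 0.21, adjusted p = 0.0933). The regulatory T cell list had a median of −0.44 over 12 genes (camera adjusted p = 0.0238, adjusted p = 0.332 with an estimated correlation), with Ikzf4 as its single fall by either adjustment, and Foxp3, the factor that defines these cells, stayed near 0.937 and 0.949 CPM. The naive and resting T cell list had a median of 0.36 over 14 genes (camera adjusted p = 0.0198, adjusted p = 0.332 with an estimated correlation). In it Tcf7 rose, and adjusted over the list alone 3 rose (Tcf7, Klf2 and Id3) and 2 fell (Satb1 and Il7r). The Tfh list, in which Bcl6 rose, had a median of 0.09 (camera adjusted p = 0.19), and adjusted over the list alone Bcl6 rose and Icos fell. The Th1 list had a median of 0.31 (adjusted p = 0.591) with no call by either adjustment. The Th17 list had a median of −0.30 over 5 genes (adjusted p = 0.256), with 1 fall adjusted over the list alone, that of the aryl hydrocarbon receptor gene Ahr (−2.95 ± 0.45, all-gene adjusted p = 0.0716). The regulatory T cell and naive list calls were lost with limma-voom and limma on FPKM, and the naive call without HU-308 replicate 1 (median 0.15). Without DMSO replicate 1 the regulatory T cell and naive medians were −0.27 and 0.58, and without DMSO replicate 2 they were −0.15 and 0.17. Lists that passed only with a library left out were Th1 (median 0.60 without HU-308 replicate 1, 0.59 without DMSO replicate 2), Th17 (−0.55 without DMSO replicate 1) and Tfh (0.41 without HU-308 replicate 2).

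Cytokine signalling genes downstream of the common gamma chain and STAT5 had the lowest median of any tested list, −1.26 over 12 genes (camera adjusted p = 3.57e-14, adjusted p = 0.332 with an estimated correlation). No member passed the all-gene threshold, while 10 of 12 fell adjusted over the list alone. Lif went from 341.2 ± 56.0 to 55.1 ± 26.7 CPM, Lta from 31.6 ± 10.4 to 2.43 ± 1.59 and Osm from 87.6 ± 20.3 to 29.3 ± 3.96 (edgeR adjusted p = 0.0646 for each). The log2 fold change of Lta was −3.7, with −3.15 without HU-308 replicate 1 and −4.59 without HU-308 replicate 2. That of Lif was −2.63, with −3.23 and −2.21 in the same 2 fits. The SOCS family had a median of −0.33 over 8 genes (camera adjusted p = 0.00888, adjusted p = 0.407 with an estimated correlation), and adjusted over the list alone 1 fell, Socs2 (505.5 ± 20.2 to 207.2 ± 36.4 CPM), which also sits in the STAT5 list. The 11 JAK and STAT genes had a median of 0.05 (adjusted p = 0.716) and no call by either adjustment. The SOCS median was −0.17 without HU-308 replicate 1 and −0.20 without DMSO replicate 2. Fibrosis-linked secreted factors had a median of −0.47 over 12 genes (camera adjusted p = 2.07e-07, adjusted p = 0.332 with an estimated correlation). There Il13 fell, and adjusted over the list alone 6 fell (Il13, Il4, Osm, Lif, Areg and Tgfb1). All of these but Tgfb1 also sit in the Th2 or STAT5 list, so this call is largely not separate from theirs. Tgfb1 went from 700.0 ± 86.2 to 495.6 ± 28.0 CPM (−0.50 ± 0.15, edgeR adjusted p = 0.18). The fibrosis median was −1.38 without HU-308 replicate 2, −0.97 without DMSO replicate 1, −0.24 without HU-308 replicate 1 and −0.29 without DMSO replicate 2, with the camera call kept in each.

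T cell activation genes had a median of −0.72 over 18 genes (camera adjusted p = 0.000314, adjusted p = 0.332 with an estimated correlation). None passed the all-gene threshold, and 6 fell adjusted over the list alone, with Irf4 at −1.63 ± 0.29, Fos at −2.56 ± 0.45 and Tnf at −1.61 ± 0.26 among them. Without HU-308 replicate 1 the median was −0.46 and the log2 fold change of Fos −3.35. Genes of cAMP and G protein signalling had a median of 0.34 over 14 genes (camera adjusted p = 0.0198, adjusted p = 0.332 with an estimated correlation). Adcy4, the adenylyl cyclase gene that fell 14.5-fold, was not among them. Adjusted over the list alone 4 rose (Rgs2, Pde4d, Pde4b and Pde4a) and 1 fell (Crem), with none past the all-gene threshold; the camera call was lost without HU-308 replicate 2 or DMSO replicate 1, where the adjusted p reached 0.153. NF-kB targets had a median of −0.02 (adjusted p = 0.591). In that list Tnfaip3 rose, and adjusted over the list alone Tnfaip3 rose and 3 fell (Nfkbiz, Bcl3 and Nfkb1). The endocannabinoid list had a median of 0.18 (adjusted p = 0.19), and adjusted over the list alone 1 rose, Faah, the hydrolase of anandamide (90.7 ± 6.20 to 195.6 ± 30.4 CPM). Type I interferon genes (median 0.15, adjusted p = 0.0605) and inhibitory receptors (median −0.02, adjusted p = 0.735) were not past the threshold; adjusted over the list alone Mx1 rose in the former and no gene was called in the latter. The interferon list passed without HU-308 replicate 1 (median 0.50) or DMSO replicate 2 (0.60).

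**Figure D3:**
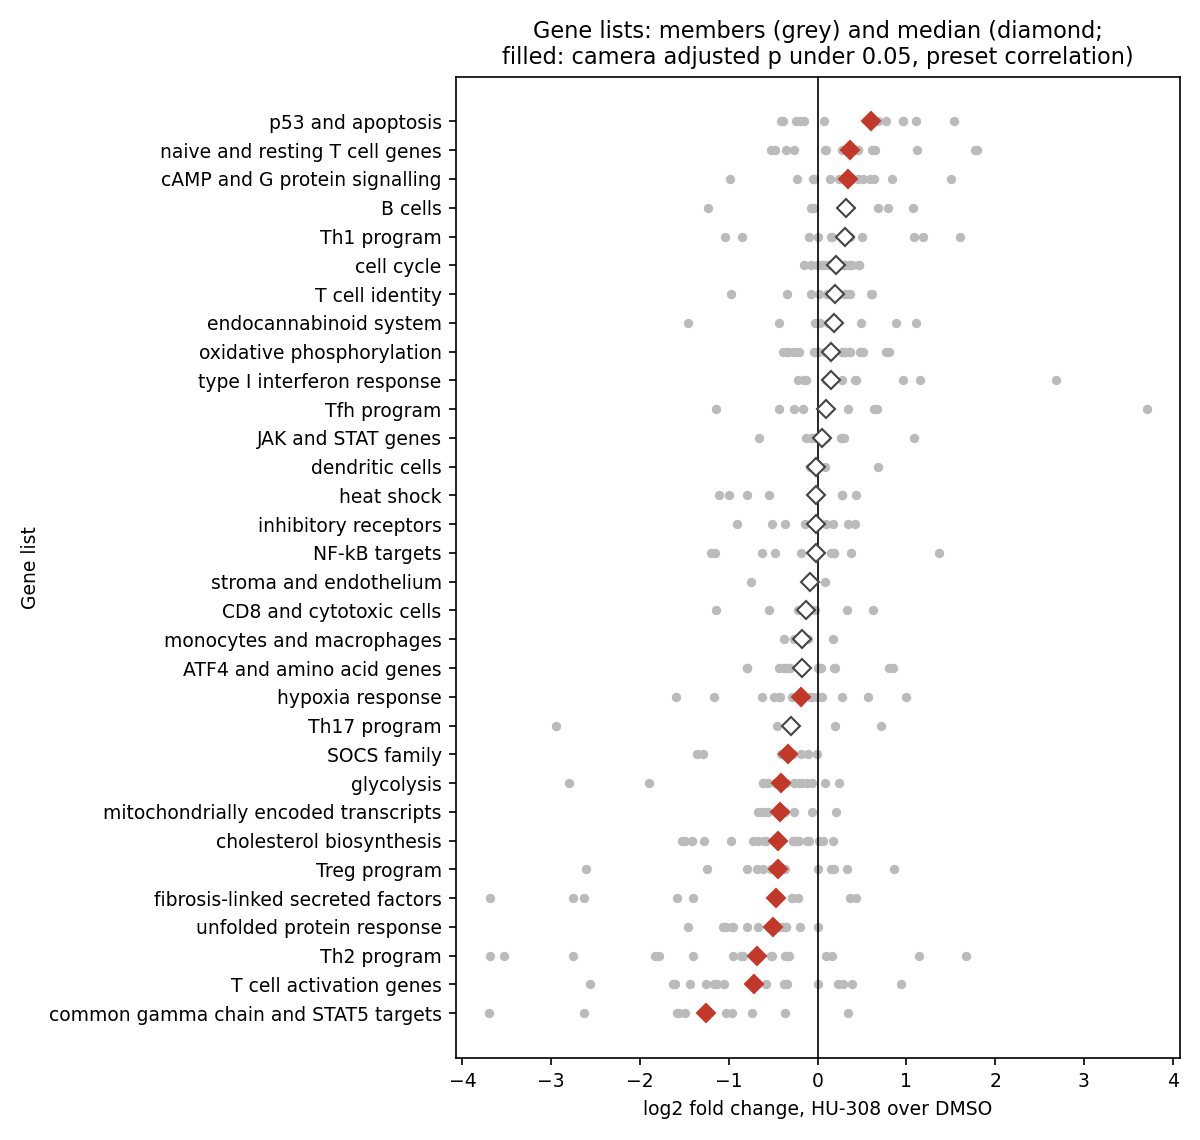
Gene lists with at least 3 tested genes. Grey points are the log2 fold changes of single members, HU-308 over DMSO, and diamonds the list medians, filled where camera's adjusted p with the preset correlation was under 0.05; medians run from −1.26 for the STAT5 list to 0.60 for the p53 list.

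The unfolded protein response had a median of −0.50 over 16 genes (camera adjusted p = 1.59e-08, adjusted p = 0.332 with an estimated correlation) and 7 falls adjusted over the list alone, with none past the all-gene threshold. The chaperone Hspa5 (BiP) went from 1655 ± 153.3 to 795.4 ± 9.07 CPM and the transcription factor Xbp1 from 785.9 ± 117.7 to 403.6 ± 54.5 CPM (edgeR adjusted p = 0.0664 and 0.0933). Cholesterol biosynthesis had a median of −0.44 over 20 genes (camera adjusted p = 8.97e-07, adjusted p = 0.332 with an estimated correlation), with 6 falls adjusted over the list alone and none over all genes. Insig1 had a log2 fold change of −1.49 ± 0.23 and Cyp51 of −1.53 ± 0.27. Glycolysis had a median of −0.41 over 17 genes (camera adjusted p = 0.000314, adjusted p = 0.332 with an estimated correlation), and adjusted over the list alone 1 fell, the hexokinase Hk2 (189.2 ± 15.97 to 27.2 ± 13.5 CPM, all-gene adjusted p = 0.0575). Gapdh is uncertain, since reads can be shared with its many pseudogenes. The hypoxia list had a median of −0.19 over 14 genes (camera adjusted p = 0.00888, adjusted p = 0.332 with an estimated correlation). In it the mitophagy receptor Bnip3 fell 3.01-fold, and adjusted over the list alone 2 fell, Bnip3 and Hif1a (1744 ± 149.9 to 773.2 ± 35.7 CPM); the list's camera call was lost without HU-308 replicate 2 and in 1 of the limma settings on FPKM, and its median was −0.29 without HU-308 replicate 1. The p53 and apoptosis list was higher, with a median of 0.60 over 14 genes (camera adjusted p = 0.0102, adjusted p = 0.466 with an estimated correlation). It had 6 rises adjusted over the list alone and none over all genes, with Bbc3 (PUMA) at 1.54 ± 0.30 and Bcl2l11 (BIM) at 0.96 ± 0.20, while Cdkn1a had a log2 fold change of −0.41 ± 0.16. The p53 camera call was lost without DMSO replicate 2 (median 0.20) and with limma on FPKM, and the median was 0.33 without HU-308 replicate 1.

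Cell cycle genes (median 0.21, camera adjusted p = 0.067), oxidative phosphorylation (0.15, 0.322), ATF4 and amino acid genes (−0.18, 0.23) and heat shock genes (−0.02, 0.0768) did not pass the list test. None of their members passed the all-gene threshold, and adjusted over the list alone Hsph1 and Hspd1 fell in the heat shock list. In some other settings cell cycle (no low-count filter, limma-voom, offsets for gene length and GC content), heat shock (no low-count filter, offsets) and ATF4 (offsets) passed camera. With a library left out they passed as follows: cell cycle without HU-308 replicate 2 (median 0.35) or DMSO replicate 1 (0.54), heat shock without HU-308 replicate 1 (−0.60) or DMSO replicate 2 (−0.07), and ATF4 without HU-308 replicate 2 (−0.33).

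Transcripts of T cells themselves were well represented in all libraries. The T cell identity list had a median of 0.20 over 14 genes (camera adjusted p = 0.334), with Cd5 rising and Cd2 falling adjusted over the list alone. Its summed level was 3990 and 4970 CPM with DMSO and 4380 and 5360 CPM with HU-308. B cell markers summed to 43.6 and 39.1 CPM with DMSO and 86.3 and 71.9 CPM with HU-308, mostly Ighm (1.07 ± 0.20, edgeR adjusted p = 0.092), which rose adjusted over the list alone; the list itself had a median of 0.32 (camera adjusted p = 0.249). Cytotoxic markers summed to 1840 and 6870 CPM with DMSO and 1490 and 3970 CPM with HU-308, mainly from Gzmb (median −0.13, adjusted p = 0.778). Markers of monocytes and macrophages (median −0.18, adjusted p = 0.722), dendritic cells (median −0.02 but mean 0.12 and camera direction higher, adjusted p = 0.735) and stroma and endothelium (−0.09, 0.435) held no call by either adjustment. NK, granulocyte and mast, and erythroid and platelet markers had too few tested genes for the list test and summed to between 0.535 and 22.3 CPM per library.

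Mitochondrially encoded transcripts, a sign of RNA or cell quality, were lower with HU-308. They made up 2.25% and 1.75% of counts with DMSO and 1.70% and 1.37% with HU-308, and the list had a median of −0.42 over 12 genes (camera adjusted p = 0.00888, adjusted p = 0.671 with an estimated correlation). No member passed by either adjustment, and the camera call was lost without HU-308 replicate 2, without DMSO replicate 1 (median −0.25) and with offsets for gene length and GC content. Ribosomal protein genes took 3.23% and 3.21% of counts with DMSO and 3.87% and 3.61% with HU-308.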

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

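The tests with offsets for length and GC content, with adjusted deviances and of shared replicate numbers were chosen only after the results were seen; the other alternatives were chosen before the data were examined. The edgeR test called 12 genes higher, 33 lower and 23 named genes. RLE factors and a log2 minimum of 1 gave the same counts. Scaling by library size only gave 8 and 12, at least 1 CPM in 2 libraries 8 and 20, and the offsets 8 and 18. Protein-coding genes alone gave 15 and 41, limma-voom 13 and 38, and adjusted deviances 14 and 41. Without the low-count filter 190 and 371 genes were called, with 63 named genes, and DESeq2 called 244 and 482, with 67 named genes. Limma on log2 FPKM called 0 higher, 0 lower and 0 named genes with either pseudocount, where 2625 and 2629 genes had an unadjusted p under 0.05. Leaving out 1 library gave 10 to 93 higher, 27 to 244 lower and 22 to 45 named genes. All 45 genes kept their sign in each of these, which the separation of their libraries made all but certain, so it is no further support. Of 32 lists, 14 passed camera with the preset correlation, 10 to 17 in the other settings and 0 with an estimated correlation, where the smallest unadjusted p was 0.0166 and fry called 1 list by direction (stroma and endothelium). The adjusted p of Il4 ranged from 2.7e-10 to 0.143 over the alternatives, that of Socs3 from 2.67e-16 to 0.372 and that of Cnr2 from 1.62e-10 to 0.499. A block for the replicate number gave 2394 higher and 2445 lower genes, 114 named genes and the lowest of those p-values, so that Socs3 passed, as did Tyk2 (adjusted p = 0.00767; up to 0.786 over the alternatives) and the cell cycle, heat shock and interferon lists, with 1 residual degree of freedom. Deviations of libraries with the same number correlated at 0.46, which could come from a shared day or batch; 2 pairs give a single such value and leave this open. Setting replicates 1 against replicates 2 gave 0 edgeR calls (1027 genes at an unadjusted p under 0.05) and the crossed split 0 (31 genes). Each side of these splits held 1 HU-308 and 1 DMSO library, so the difference between the groups widened the spread and made calls unlikely. The 0 counts are therefore no check on the 45 calls. Camera nevertheless called 6 lists between replicates 2 and 1: lower were cell cycle (median −0.46, limma adjusted p = 2.06e-08), mitochondrial transcripts (−0.32, 0.00121) and heat shock (−0.40, 0.0238), and higher were interferon (0.38, 0.00129), T cell identity (0.38, 0.00197) and Th1 (1.14, 0.0413), so these lists vary between libraries of a group about as much as between groups or more.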

Other observations

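The lists of FOXO-induced genes and ribosome biogenesis, the offsets for length and GC content, and the tests of Il13 against Il4 and of the T cell identity list were chosen only after the results were seen. Of 20 genes of ribosome biogenesis, 19 had lower values with HU-308 and the median log2 fold change was −1.09 (camera adjusted p = 2.04e-24, adjusted p = 0.236 with an estimated correlation; limma, adjusted over these 2 lists). None passed the all-gene threshold, and 18 fell adjusted over the list alone. Polr1b, a subunit of RNA polymerase I, went from 75.3 ± 16.65 to 20.7 ± 3.23 CPM (edgeR adjusted p = 0.0506) and Rrp12 from 101.0 ± 22.35 to 30.1 ± 4.00 CPM (edgeR adjusted p = 0.0519). Of 12 FOXO-induced genes 9 were higher, with a median of 0.58 (camera adjusted p = 0.00746, adjusted p = 0.428 with an estimated correlation); none passed over all genes, and 7 rose and 3 fell (Irs2, Gabarapl1 and Cited2) adjusted over the list alone. Pik3ip1, an inhibitor of PI3K, went from 11.03 ± 3.11 to 32.4 ± 7.53 CPM (edgeR adjusted p = 0.089).

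Weaker PI3K, AKT and growth signalling with HU-308 is a hypothesis that prompted both lists and was not itself tested. The ribosome biogenesis median lay at percentile 0.01 of 10000 matched random lists, the smallest possible, and the FOXO median at percentile 100, which shows only that these lists moved more than random ones. With offsets for length and GC content the medians were −1.06 and 0.60. Neither list passed camera with an estimated correlation, which has little power with 2 residual degrees of freedom. Whether the pattern reflects genes that vary together between these 4 libraries remains open.

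The lower Th2 cytokines may have causes other than altered transcription per cell. A lower share of Th2 cells as the whole cause would lower Il13 and Il4 alike only if the remaining cells made neither. Their log2 fold changes differed by −2.29, against 2 combined SE of 0.78. Remaining cells that made Il4 but little Il13 would also give such a difference, so a shift in cell shares stays open. The T cell identity list had a median of 0.20, where dilution by other cells would lower it. The median of Il4, Il5, Il10 and Il13 was −2.64 with offsets for length and GC content. Among 16 other tested genes within 500 kb of the cluster, 9 were lower and the median was −0.25, but Kif3a, next to Il4, stood at −1.54 ± 0.23 (edgeR adjusted p = 0.0679) and Rad50, between Il13 and Il5, at −0.55 ± 0.16, so a change limited to the nearest genes remains open.

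Lower STAT5 targets, unfolded protein response and cholesterol genes could come from the abundance, length or GC content of the member genes. Each list's median lay at percentile 0.01 of 10000 random lists matched for abundance and length, the smallest possible. With offsets for length and GC content the medians were −1.20, −0.57 and −0.49. A difference in handling between the groups was not tested, since the labels give no batch.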
